A study of Mus musculus with 15 samples.

How the data were processed

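The data are RNA-seq profiles of mouse brain tumour tissue from 15 samples, 3 in each of 5 groups. Per the labels' protocols, tumour pieces were kept frozen in trizol, RNA was purified on RNeasy columns, and libraries were made with a stranded poly(A) kit (TruSeq) from 300 ng of total RNA. The submitters' processing notes name the genome build mm10 and the tools STAR 2.5.0a, FastQC 0.11.7, MultiQC 1.11 and DESeq2 1.30.1, with no roles given. The tool that counted reads per gene, its strand setting and the annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes are uncertain. How the loss or gain of Sox9 function was made is not in the labels.

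The authors deposited 3 tables of 6 libraries and 24421 genes each, 1 per comparison (HGG Sox9-LOF, HGG Sox9-GOF and EPN Sox9-GOF, each with its controls). The deposited values are a signal per gene, namely read counts divided by a size factor for each library, as the values show. Each value is a whole multiple of what 1 read is worth in its library, within 0.001 read, for 100% of values. Factors recomputed from the recovered reads by DESeq2's median of ratios equalled the deposited ones (ratio 1), separately for each table. In the library labelled Sox9-LOF 3 a read is worth 0.998, too close to 1 for the automated test of whole reads, and its reads were recovered in the same way. The HGG control reads were identical in both HGG tables for 24421 of 24421 genes. The tables also hold 6 empty unnamed columns, and 0 columns of samples were left unused. Names of 27 genes had been turned into dates, and these genes were kept in the tests and never named. Of 24421 names, 24308 matched a current or older mouse symbol, 23615 of them a current one. Coordinates of Sox9 come from a GENCODE annotation of GRCm38, the same build as mm10.

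The depth per library was 4665428 to 14119140 recovered reads, with a median of 10578708. Each library was placed in its group by its title, which also gives the replicate number. Replicates were compared before averaging, and no 2 libraries were identical.

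The design had assumed raw counts and edgeR as the main test. Because the deposited values were normalized, the main test was limma 3.58.1 (trended variance) in R 4.3.3 on log2(normalized count + 1), over genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. The pseudocount and the minimum were set after the values had been seen. Groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Each main comparison used the 6 libraries of its table. The difference between the 2 gain-of-function effects was a contrast of 4 group means on the deposited scales. The comparison of controls, the group means and the library scores used recovered reads rescaled together by the median of ratios. A score is the mean, over the measured members of a list, of log2(rescaled count + 1) minus the mean of the gene over the 15 libraries. For genes with 1 to 3 reads in a group, the ratio with its 95% counting interval is given, and for 0 reads a floor of 3 reads over the group.

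The 26 gene lists held 527 members, of which 520 matched the tables, with at least 3 measured needed for a test. They cover chondrogenic targets of SOX9, astrocyte, oligodendrocyte precursor, mature oligodendrocyte, neuron, ependymal and cilia, neural stem, cell cycle, microglia, lymphocyte, neutrophil, interferon, endothelial, pericyte, collagen and mesenchymal, NF-kB, ZFTA-RELA ependymoma, histone acetylation, hypoxia, WNT, NOTCH, ERK feedback, p53, immediate early, erythroid and choroid plexus genes. Some genes stand in 2 lists, and tumour cells of glial origin can express astrocyte, precursor and neural stem genes themselves. The erythroid list was tested only where EPN libraries took part. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Named genes were Sox9, Nf1, Trp53, Rela and Zfta, the 10 largest called changes in each direction of a main comparison (there were 0), up to 4 members per list by smallest adjusted p, the 5 largest called differences in each direction between the models and between the controls (for all of these a mean log2 CPM of at least 1, and groups that do not overlap, except between the models, leaving out predicted models), and called members of the Sox family. Some of these genes are not reported here, but they enter the counts of called genes and the list tests. Other genes are said to be chosen after their values were seen.

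Replicate numbers run through all groups in the labels. Whether they pair the samples was checked by correlating the deviations of same-numbered libraries from their group means. These were 0.18, 0.44 and 0.22 for HGG Sox9-GOF and its controls, all over 0.1, so the numbers may pair those samples. With 3 libraries per group this check cannot show that they do, and the labels do not state it. In the other comparisons the numbers did not pass this check.

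The alternatives were edgeR 4.0.16 (TMM or median-of-ratios factors) and DESeq2 1.42.0 on the recovered reads, no filter, a stricter filter (a CPM of 1 in 3 libraries), a fold threshold of 1 on the log2 scale, a spread shared by all 15 libraries, a replicate block, and leaving out each library in turn. Chosen after the data were seen were edgeR's own filter, pseudocounts of 0.5 and 8, library weights, TMM scaling, a spline correction for GC content and length (5 degrees of freedom, GC known for 99.28% of genes) with and without the block, and a spread shared by the 9 HGG libraries. The direct comparison of HGG Sox9-GOF with the libraries labelled Sox9-LOF was also added then. For the shared HGG controls, unchanged groups were simulated 100 times against those controls, without any pairing by replicate number. All steps were tested on simulated data with 200 genes changed by known amounts.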

Results

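Gene expression was measured in mouse brain tumours of 2 models by strand-specific sequencing of poly(A) RNA. HGG stands for high-grade glioma, a fast-growing glial tumour, and EPN for ependymoma, a tumour with features of the cells that line the ventricles. The 15 libraries fall into 5 groups of 3: HGG controls, HGG labelled Sox9-LOF (loss of function), HGG labelled Sox9-GOF (gain of function), EPN controls and EPN labelled Sox9-GOF. The title of the series asks whether Sox9, a transcription factor of glial and cartilage development, drives tumour subtypes in different directions. The reads assigned to genes were 12160281, 4665428 and 13830743 in HGG controls 1, 2 and 3, and 7941469, 8322482 and 8815013 in the libraries labelled Sox9-LOF. They were 13273065, 12432289 and 10578708 in the HGG Sox9-GOF libraries, 9443466, 9084782 and 6266613 in the EPN controls, and 14119140, 12067101 and 10957005 in the EPN Sox9-GOF libraries. The same 3 HGG control libraries served both HGG comparisons. Sex-linked genes, given under the other observations, were unevenly spread between the groups, and no test took sex into account. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples. Confidence intervals and floors cover counting error only.

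Sox9 (ENSMUSG00000000567.5, protein coding, plus strand of chromosome 11, positions 112782224 to 112787760 in mm10) was read in every library first, since it checks the labels. Its mean normalized count was 271 ± 47.6 (SD, n = 3) in the HGG controls, 571 ± 172 in the libraries labelled Sox9-LOF and 1401 ± 131 in the HGG Sox9-GOF libraries. In EPN it was 1091 ± 84.4 in the controls and 2194 ± 446 with Sox9-GOF. All 3 libraries labelled Sox9-LOF held more Sox9 than every HGG control (739, 579 and 395 against 218, 285 and 310). Their label therefore runs against the level of the Sox9 transcript, and they are called the libraries labelled Sox9-LOF throughout. The log2 fold change against control was 1.03 (SE 0.29, limma adjusted p = 0.184) in those libraries, 2.40 (SE 0.20, adjusted p = 0.0590) in HGG Sox9-GOF, which is 5.28-fold, and 1.04 (SE 0.18, adjusted p = 0.133) in EPN Sox9-GOF, which is 2.05-fold. None of the 3 passed limma at an adjusted p of 0.05. By DESeq2 all 3 passed, with adjusted p-values of 0.0391, 1.88e-18 and 0.000485. With the spread shared by all 15 libraries, limma gave adjusted p-values of 0.0205 for the libraries labelled Sox9-LOF, 0.000703 for HGG Sox9-GOF and 0.0623 for EPN Sox9-GOF, which did not pass. An exact two-sided permutation test on 3 against 3 libraries gave p = 0.1 in each comparison, the smallest value this design allows.

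**Figure D1:**
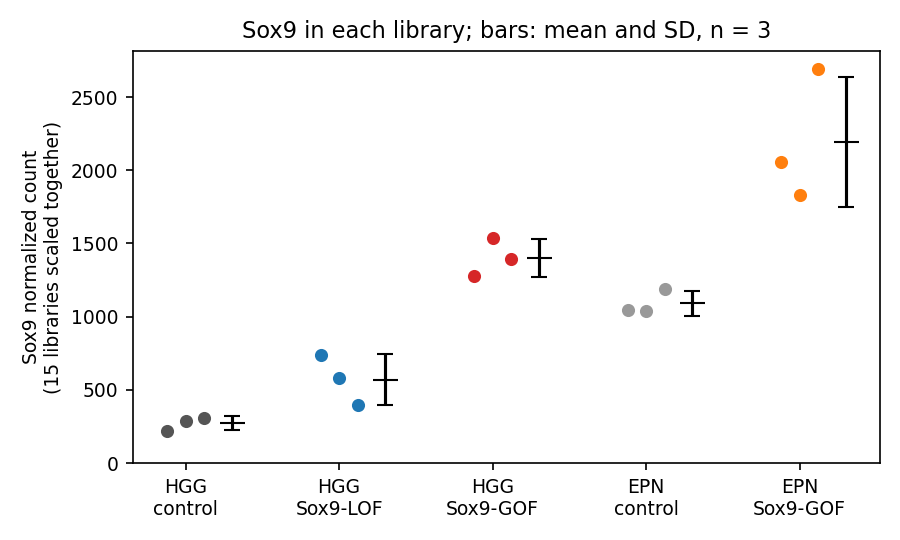
Normalized counts of Sox9 in the 15 libraries, all scaled together, by group, with 1 dot per library and the mean with its SD as bars. The libraries labelled Sox9-LOF (395 to 739) sit above all HGG controls (218 to 310), and the HGG Sox9-GOF libraries sit above both.

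The first comparison asks what differs in the HGG libraries labelled Sox9-LOF, whose Sox9 transcript was higher than in the controls. Astrocyte markers were higher as a group, with 22 of 23 measured members positive and a median log2 fold change of 0.91, including the water channel Aqp4 (3.14, SE 1.04) and the filament gene Gfap (1.46, SE 0.59). Neuron markers were higher by a median of 0.71 (21 of 23 positive), including Gad2, an enzyme of GABA synthesis (3.27, SE 0.99), and the microtubule gene Map2 (1.09, SE 0.34). Ependymal and motile cilia genes were higher by 0.81 (20 of 24 positive), and feedback genes of receptor tyrosine kinase and ERK signalling by 0.60 (15 of 17 positive), among them Spred1 (1.28, SE 0.22) and Spry2 (0.89, SE 0.23). Lymphocyte markers were lower by a median of -2.56 with 0 of 18 members positive, for example the B cell receptor gene Cd79a (-3.79, SE 1.41). Interferon response and antigen presentation genes were lower by -0.90 (27 of 31 negative), led by the MHC class I gene H2-D1 (-3.48, SE 0.57), and NF-kB target genes by -0.65 (15 of 20 negative), led by Nfkb2 (-1.73, SE 0.41) and Relb (-1.48, SE 0.42).

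These 7 lists passed camera with adjusted p-values of 0.00505 for astrocyte and lymphocyte markers, 0.00674 for interferon genes, 0.00929 for the ERK feedback genes, and 0.0436 for neuron markers, cilia genes and NF-kB targets. Each has an adjusted p = 0.986 with an estimated correlation between its genes, so none of the 7 calls holds then. The calls and medians depended on single libraries, with the adjusted p given first. Without HGG control 1 they were 0.115 and 0.21 for astrocyte markers, 0.840 and 0.13 for neuron markers (where the direction in camera turned), 0.157 and -0.42 for interferon genes and 0.265 and -0.32 for NF-kB targets, lymphocyte markers had an adjusted p of 0.115, and the median of cilia genes was 1.31. Without HGG control 2 neuron markers had an adjusted p of 0.0770, cilia genes had 0.569 with a median of about 0 (-0.0050), and the medians were 1.41 for astrocyte markers, -4.55 for lymphocyte markers, -1.79 for interferon genes and -1.22 for NF-kB targets. Without HGG control 3 they were 0.159 and -1.37 for lymphocyte markers, 0.224 and -0.28 for interferon genes, 0.305 and -0.33 for NF-kB targets and 0.159 and 0.28 for ERK feedback genes, cilia genes had an adjusted p of 0.0851, and the neuron median was 1.67. Without the library labelled Sox9-LOF 1 the adjusted p was 0.179 for neuron markers (median 0.33), 0.0582 for interferon genes and 0.0641 for NF-kB targets. Without that labelled Sox9-LOF 2 the neuron median was 1.19, and without that labelled Sox9-LOF 3 the adjusted p was 0.0991 for neuron markers, 0.263 for cilia genes (median 0.40) and 0.0909 for NF-kB targets. With a pseudocount of 8 the adjusted p was 0.0501 for neuron markers and NF-kB targets and 0.0639 for cilia genes (median 0.39), and with TMM scaling 0.0508 for NF-kB targets. Signs of RNA or library quality, named after their values were seen, stood lower than in the HGG controls: the annotated microRNA Mir6236 had 244 ± 62.2 normalized counts (SD, n = 3) against 2539 ± 808, Lars2 had 3091 ± 634 against 8937 ± 1144, and the ribosomal RNA precursor Rn45s 8871 ± 1526 against 18222 ± 8503 (limma adjusted p = 0.143 for Lars2 and 0.335 for Rn45s, and Mir6236 did not pass either).

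No single gene passed limma. The count was 0 of 14861, with 2564 genes at an unadjusted p under 0.05 (1355 higher, 1209 lower), 0 called by edgeR and 1221 by DESeq2 (584 higher, 637 lower). The smallest adjusted p was 0.0569, for Scand1 (-3.85, SE 0.28), which was named after its values were seen. Without HGG control 2 limma called 6 genes, with Scand1 then at an adjusted p of 0.0478, and without the library labelled Sox9-LOF 2 it called 1. Adjusted over the list alone, 1 ERK feedback gene (Spred1) was higher, 1 interferon gene (H2-D1) was lower, and of the histone acetylation genes Gatad2b was higher and Hdac10 lower. The groups did not overlap for 3640 genes, 24.5% against the 10% that splits of the 6 libraries into groups of 3 give on average. Genes are correlated, so a single split can lie far from that average, and the excess was not tested. With the spread shared by all 15 libraries 1108 genes were called, with that of the 9 HGG libraries 323, and with library weights 1. The HGG controls stood apart from each other: their pairwise correlations across genes were 0.819 to 0.861, against 0.930 to 0.965 within the other groups. The mean lymphocyte marker score was 2.70, -2.73 and 3.39 in HGG controls 1, 2 and 3, and the choroid plexus score, from genes of the tissue that makes cerebrospinal fluid, was 5.03, -1.41 and -1.30. Genes of higher GC content had lower fold changes across genes, which are not independent replicates (Spearman rho -0.473 in this comparison, -0.578 with HGG Sox9-GOF and -0.00867 with EPN Sox9-GOF).

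Other fixed lists did not pass camera in the libraries labelled Sox9-LOF. The cartilage genes known as targets of SOX9 had a median of -0.49 (10 of 15 negative, camera adjusted p = 0.385), NOTCH pathway genes -0.43 (adjusted p = 0.385), p53 targets 0.27 (adjusted p = 0.588), neural stem and radial glia genes 0.11 (adjusted p = 0.929), histone acetylation genes -0.08 (adjusted p = 0.758) and WNT targets -0.21 (adjusted p = 0.797). Of the genes often altered in such models, the tumour suppressors Nf1 and Trp53 had log2 fold changes of 0.33 and -0.77, and Rela and Zfta, the partners of the ependymoma fusion, -0.82 and -0.86. None passed limma (adjusted p = 0.563, 0.393, 0.226 and 0.217).

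With Sox9-GOF in HGG, immediate early genes, which respond within minutes to stimuli, were lower by a median log2 fold change of -1.10 (14 of 16 negative), including Klf2 (-2.14, SE 0.39), Ier2 (-1.59, SE 0.29) and Egr1 (-1.54, SE 0.31). Hypoxia and glycolysis genes were lower by -0.57 (17 of 21 negative), with the collagen hydroxylase P4ha2 at -1.74 (SE 0.54) and the glucose transporter Slc2a1 at -1.17 (SE 0.38). Microglia and macrophage markers were higher by 0.73 (21 of 23 positive), including the microglial receptor P2ry12 (2.18, SE 0.57) and the integrin Itgam (1.27, SE 0.48). Cartilage genes had a median of 0.99 (11 of 16 positive) and did not pass without a correction for GC content, with the cartilage matrix genes Lect1 at 2.56 (SE 0.62) and Ucma at 2.88 (SE 0.74). Histone acetylation genes went both ways around a median of -0.11, with the deacetylase Hdac7 at -1.80 (SE 0.21), the deacetylase complex genes Mta1 at -1.35 (SE 0.20) and Gatad2b at 1.85 (SE 0.24), and the acetyltransferase Kat2a at -1.03 (SE 0.17).

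Camera's adjusted p was 0.000829 for immediate early genes (0.603 with an estimated correlation) and 0.0293 for both hypoxia genes and microglia markers (adjusted p = 0.918 with an estimated correlation for each). Microglia markers lost the call without HGG control 2 (adjusted p = 0.554, median 0.25) or HGG Sox9-GOF 3 (0.0918), and had a median of 1.24 without HGG control 3. Hypoxia genes lost it without HGG control 1 (adjusted p = 0.404, median -0.24), HGG control 3 (0.0629) or HGG Sox9-GOF 2 (0.0829), and had a median of -1.05 without HGG control 2. Beside these lists, Mir6236 had 485 ± 352 normalized counts against 2539 ± 808 in the controls, Lars2 5105 ± 3354 against 8937 ± 1144 and Rn45s 31865 ± 30370 against 18222 ± 8503 (limma adjusted p = 0.0716, 0.285 and 0.820). Astrocyte markers had a median of 0.66 (18 of 23 positive, adjusted p = 0.211), which became 0.0187 with the replicate number as a block (adjusted p = 0.840 with the block and an estimated correlation). After a correction for GC content and length, cartilage genes (adjusted p = 0.0495), astrocyte markers (0.0249) and neuron markers (0.0161) passed as well, all upward, and with the block added they had 0.0454, 0.000157 and 0.00969 (adjusted p = 0.956 for each with an estimated correlation after the correction, and 0.866 with the block). Adjusted over the list alone, 8 immediate early genes were lower, 3 histone acetylation genes were higher and 7 lower, 2 cartilage genes were higher and 1 lower, 2 WNT targets were lower, 1 p53 target (Eda2r) was higher, 1 choroid plexus marker (Sostdc1) was lower and Rela was lower. The adjusted p of the lists that did not pass was 0.271 for cartilage genes, 0.308 for histone acetylation genes, 0.211 for neuron markers (median 0.56), 0.211 for genes described in ZFTA-RELA ependymoma (median -0.50), 0.322 for lymphocyte markers (median -0.59) and 0.322 for choroid plexus markers (median -0.72).

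No gene passed limma in this comparison. The count was 0 of 15092, with 3420 at an unadjusted p under 0.05 (1764 higher, 1656 lower), 0 called by edgeR and 2174 by DESeq2 (1077 higher, 1097 lower). The groups did not overlap for 4600 genes, 30.5% against the average of 10% over splits, an excess that was not tested. The smallest adjusted p was 0.0590, shared by Sox9, Hdac7, Gatad2b and Scand1 (-3.30, SE 0.28) among others. With the spread shared by all 15 libraries 2253 genes were called, and with that of the 9 HGG libraries 1259. In each library, the deviation of a gene from its mean over the 15 libraries was correlated with GC content across genes at 0.214, 0.360 and 0.296 in the HGG controls and at -0.282, -0.286 and -0.226 in the HGG Sox9-GOF libraries (Spearman rho). The spread between replicates was larger in the HGG controls (median SD 0.456 on the log2 scale) than with Sox9-GOF (0.299). Rela had a log2 fold change of -1.20 (adjusted p = 0.0594 in limma), and Nf1, Trp53 and Zfta had 0.72, -1.06 and -0.83.

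**Figure D2:**
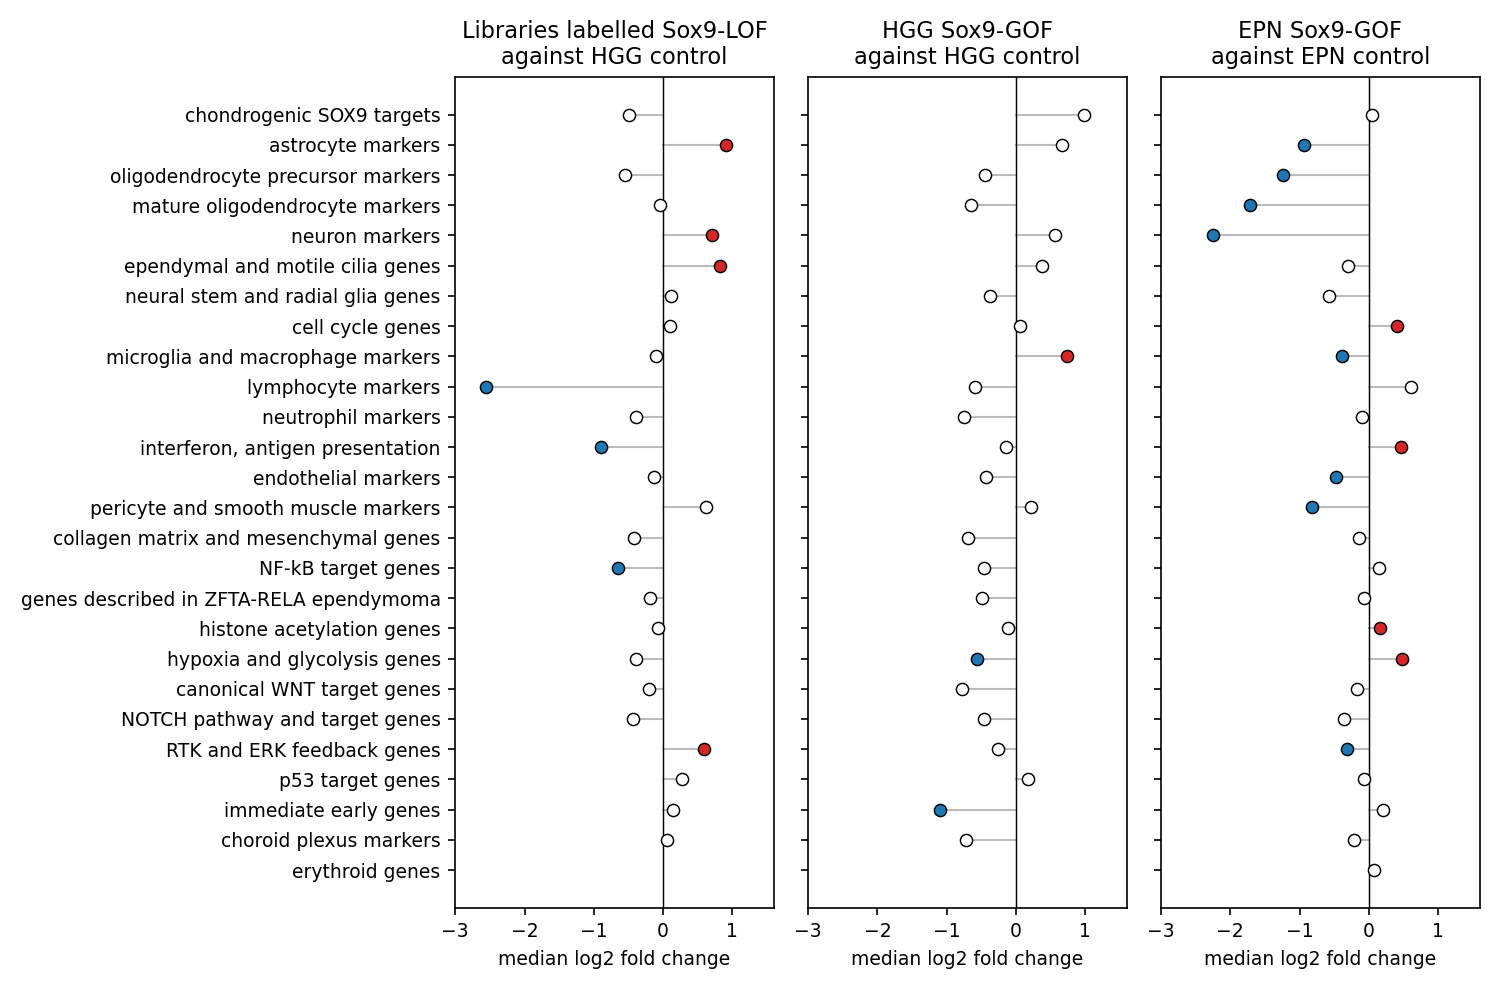
Median log2 fold change of the fixed gene lists in the libraries labelled Sox9-LOF, in HGG Sox9-GOF and in EPN Sox9-GOF, each against its controls. Filled points have a camera adjusted p under 0.05 with the preset correlation, red for higher and blue for lower, which is 7, 3 and 12 lists, and 0 with an estimated correlation.

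Fold changes in the libraries labelled Sox9-LOF and in HGG Sox9-GOF went together, with Sox9 higher in both. Their correlation across 14781 genes was 0.807, and 83.0% of genes had the same sign. Scand1 had a mean of 763 ± 196 normalized counts (SD, n = 3) in the controls, 51.3 ± 7.81 in the libraries labelled Sox9-LOF and 74.8 ± 14.8 in HGG Sox9-GOF, without passing limma in either. The comparisons share their controls, and unchanged groups simulated against those controls gave a median correlation of 0.808 (95% range -0.05 to 0.98) and a same-sign share of 78.8%. The covariance was 0.533, against a mean of 0.348 in 100 simulations, of which 21 were as large, and it was 0.805 without HGG control 3. By limma 0 genes were called in both. At an unadjusted p under 0.05 in both, 1881 genes had the same direction and 1 the opposite, against a median of 18.5 with the same direction in the simulations, 9 of which were as large. DESeq2 called 850 genes in both, 442 higher and 408 lower with 0 opposite. In 20 simulations of unchanged groups it called a median of 0 and at most 1378 in the same direction and 0 opposite, and independent lists would share 32.5 higher and 36.1 lower. The 3 controls cannot be split into parts of 2. The correlation, the covariance and the DESeq2 overlap lay within the range of the simulations, so all or part of the agreement may come from the shared controls. After a correction for GC content and length the correlation was 0.751, against a median of 0.698 in the simulations (39 of 100 as large), and the covariance was 0.358 against a mean of 0.234 (19 of 100 as large), with 0.569 without HGG control 2 and 0.630 without HGG control 3. At an unadjusted p under 0.05 in both, 661 genes then had the same direction.

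**Figure D3:**
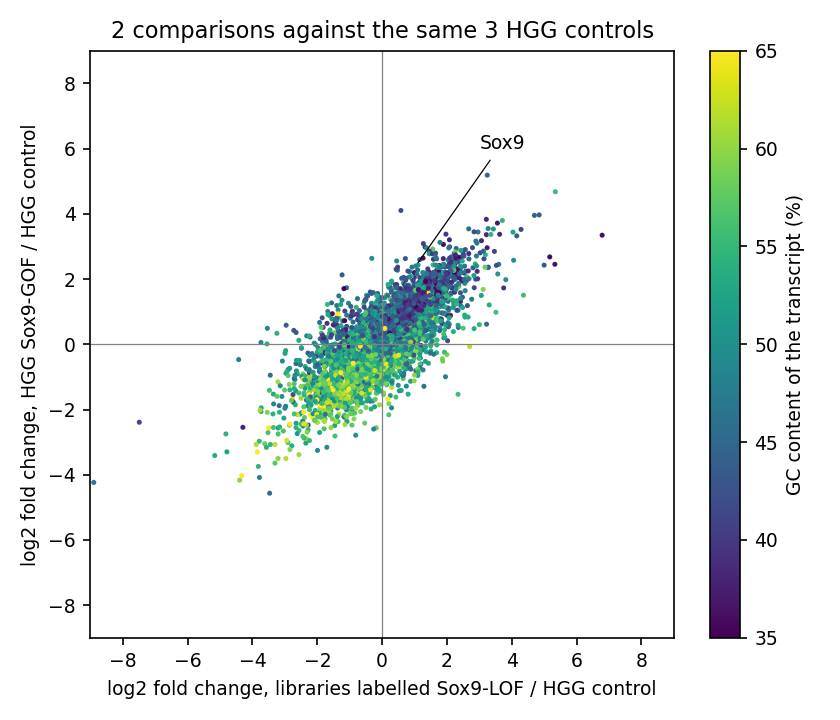
Log2 fold change of each gene in HGG Sox9-GOF against that in the libraries labelled Sox9-LOF, both against the same 3 HGG controls, coloured by the GC content of the gene in percent. The correlation across 14781 genes is 0.807, and Sox9 is marked at 1.03 and 2.40.

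With Sox9-GOF in EPN, genes of brain cell types were lower. Neuron markers had a median log2 fold change of -2.25 (22 of 23 negative), including the cortical transcription factor Tbr1 (-2.68, SE 0.61), the synaptic kinase Camk2a (-2.25, SE 0.57) and Dcx of migrating neurons (-1.72, SE 0.44). Astrocyte markers were lower by -0.93 (22 of 23 negative), with the glutamate transporter Slc1a2 at -2.24 (SE 0.27) and the connexin Gjb6 at -2.29 (SE 0.35). Oligodendrocyte precursor markers were lower by -1.24 (14 of 16 negative), such as Ptprz1 (-1.81, SE 0.32), and mature oligodendrocyte markers by -1.72 (13 of 16 negative), such as the myelin lipid enzyme Ugt8a (-1.76, SE 0.37). Endothelial markers were lower by -0.47 (15 of 18 negative), pericyte and smooth muscle markers by -0.81 (11 of 12 negative), microglia and macrophage markers by -0.39 (21 of 23 negative) and ERK feedback genes by -0.32 (12 of 17 negative). Cell cycle genes were higher by 0.41 with all 36 members positive, including Pcna of the replication fork (0.43, SE 0.18) and the helicase gene Mcm6 (0.71, SE 0.31). Interferon and antigen presentation genes were higher by 0.47 (30 of 31 positive), hypoxia and glycolysis genes by 0.47 (17 of 21 positive), including Ldha (0.71, SE 0.22), and histone acetylation genes by 0.16 (35 of 42 positive). The ribosomal RNA precursor Rn45s, which poly(A) selection should largely remove and which was named after its values were seen, differed between the same groups, with normalized counts of 38128, 20437 and 102250 in EPN Sox9-GOF 1, 2 and 3 against 7518, 6327 and 7346 in the EPN controls (log2 fold change 2.66, SE 0.54, limma adjusted p = 0.147). Mir6236 had 777 ± 540 against 191 ± 67.5 and Lars2 7031 ± 5061 against 2306 ± 475 (adjusted p = 0.179 and 0.242).

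These 12 lists passed camera. The adjusted p was 8.71e-12 for neuron, 9.21e-12 for astrocyte, 4.64e-06 for oligodendrocyte precursor and 1.63e-05 for mature oligodendrocyte markers, each with an adjusted p = 0.519 with an estimated correlation. It was 1.74e-05 for cell cycle genes, 0.00120 for interferon genes and 0.0130 for microglia markers (adjusted p = 0.716 with an estimated correlation for each). It was 0.00120 for endothelial markers, 0.00306 for hypoxia genes and 0.0128 for histone acetylation genes (adjusted p = 0.680 with an estimated correlation), 0.00989 for pericyte markers (adjusted p = 0.576 with an estimated correlation) and 0.0439 for ERK feedback genes (adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone, 19 neuron, 12 astrocyte, 8 oligodendrocyte precursor and 4 mature oligodendrocyte markers and 2 WNT targets were lower. The adjusted p of cell cycle genes was 0.285 without EPN Sox9-GOF 1, whose cell cycle score of 1.27 stood above the 0.33 and 0.21 of the other Sox9-GOF libraries, and the median was then 0.06. It was 0.27 without EPN control 3 and 0.63 without Sox9-GOF 3. The calls of 7 other lists in EPN were lost without 1 library. Camera's adjusted p for microglia markers was 0.116 without EPN control 1 (median -0.17), 0.141 without Sox9-GOF 1 and 0.531 without Sox9-GOF 3 (median 0.05), and the median was -0.65 without EPN control 3 and -0.88 without Sox9-GOF 2. For interferon genes it was 0.534 without EPN control 3 (median 0.06), 0.149 without Sox9-GOF 1 (median 0.23) and 0.0712 without Sox9-GOF 2, and the median was 0.71 without EPN control 2 and 0.80 without Sox9-GOF 3. For histone acetylation genes it was 0.0626 without EPN control 3, 0.0646 without Sox9-GOF 1 and 0.0803 without Sox9-GOF 3, and the median was 0.25 without Sox9-GOF 2. For ERK feedback genes it was 0.0977 without EPN control 1, 0.0688 without EPN control 2, 0.142 without Sox9-GOF 2, 0.0899 without Sox9-GOF 3 and 0.0747 with a correction for GC content and length (median -0.15). It was 0.105 for endothelial markers (median -0.25) and 0.0921 for hypoxia genes (median 0.28) without Sox9-GOF 3, and 0.0731 for pericyte markers without Sox9-GOF 1 (median -0.31), whose median was -1.25 without Sox9-GOF 2. Neuron, astrocyte and both oligodendrocyte lists passed with each library left out in turn, with medians of -1.43 for neuron and -1.01 for mature oligodendrocyte markers without Sox9-GOF 3 and -1.55 for astrocyte markers without Sox9-GOF 2.

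Other lists did not pass camera in EPN. These were neural stem genes (median -0.58, adjusted p = 0.0571), NOTCH pathway genes (-0.35, 0.0797), lymphocyte markers (0.61, 0.144), cilia genes (-0.31, 0.241), cartilage genes (0.05, 0.617), collagen genes (-0.15, 0.520), NF-kB targets (0.15, 0.520) and genes described in ZFTA-RELA ependymoma (-0.07, 0.814).

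No gene passed limma in EPN. The count was 0 of 14591, with 2196 at an unadjusted p under 0.05 (629 higher, 1567 lower), 0 called by edgeR and 851 by DESeq2 (106 higher, 745 lower). The groups did not overlap for 3209 genes, 22.0% against the average of 10% over splits, an excess that was not tested. The smallest adjusted p was 0.133, for Sox9 and Miat among others, the latter a long noncoding RNA named after its values were seen. With the spread shared by all 15 libraries 129 genes were called (4 higher, 125 lower), and 5 without EPN control 1. The log2 fold changes of Nf1, Trp53, Rela and Zfta were 0.04, -0.18, 0.22 and 0.44.

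**Figure D4:**
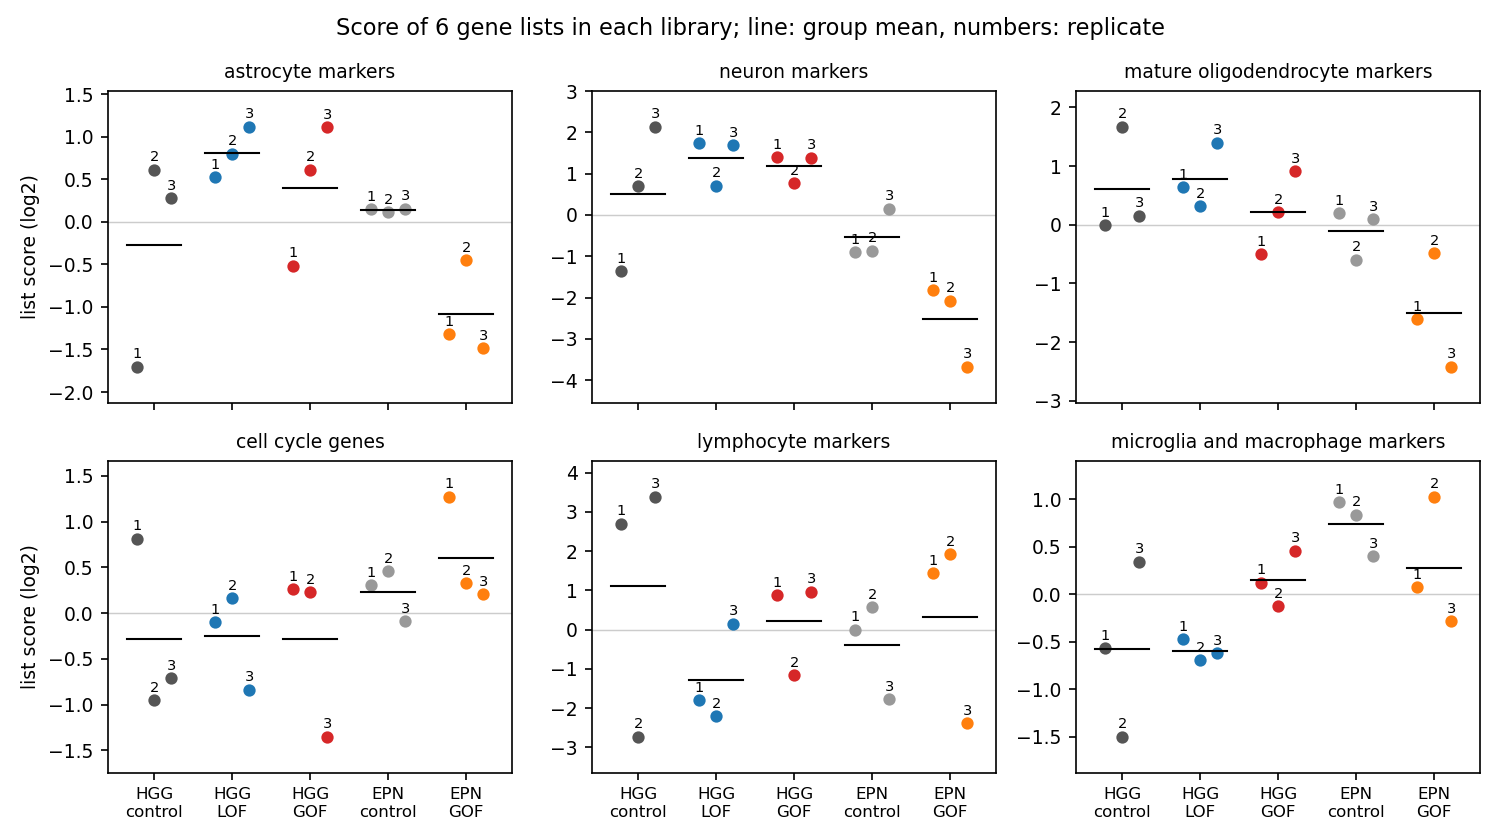
Mean score per library of 6 gene lists (log2 normalized count minus the mean of the gene over all 15 libraries), with the digit giving the replicate and the line the group mean. Neuron, astrocyte and mature oligodendrocyte scores are lower in the EPN Sox9-GOF libraries than in the EPN controls, and the lymphocyte score of HGG control 2 (-2.73) lies far below those of HGG controls 1 and 3.

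The effect of Sox9-GOF was then compared between the models, as the change in EPN minus the change in HGG. Neuron markers differed by a median of -2.92 (22 of 23 negative), astrocyte markers by -1.55 (22 of 23 negative) and microglia markers by -1.24 (21 of 23 negative), while hypoxia genes differed by 1.04 (20 of 21 positive) and immediate early genes by 1.46 (12 of 16 positive). Among histone acetylation genes, with a median of 0.32 (29 of 42 positive), Hdac7 (1.87, SE 0.29, limma adjusted p = 0.0178), Mta1 (1.73, SE 0.24, 0.0145) and Kat2a (1.08, SE 0.21, 0.0224) differed upward and Gatad2b downward (-1.61, SE 0.35, 0.0291). Of the immediate early genes 3 were called, namely Ier2 (2.37), Egr1 (1.96) and Klf2 (2.04), and of the neuron and microglia markers Map2 (-1.83) and P2ry12 (-2.98). Among named gene models with a mean log2 CPM of at least 1, the largest upward differences were Scand1 (4.50, SE 0.49), the annotated microRNA Mir6236 (4.44, SE 0.83) and Dmrta2, a transcription factor of the developing cortex (3.82, SE 0.90). The largest downward ones among the same models were the neuropeptide Gal (-7.33, SE 1.26) and the matrix protein Tnn (-6.42, SE 1.53). Gal went from 3.15 ± 4.85 to 68.2 ± 41.7 normalized counts (SD, n = 3) in HGG and from 41.2 ± 29.3 to 5.23 ± 3.40 in EPN. Sox9 itself differed by -1.36 (SE 0.26, adjusted p = 0.0233). This is a difference of log2 fold changes from unlike starting levels. Mean normalized counts of Sox9 went from 271 to 1401 in HGG and from 1091 to 2194 in EPN, so the value does not show a smaller gain in counts in EPN. Signs of RNA or library quality differed beside these lists. Mir6236 went from 2539 ± 808 to 485 ± 352 normalized counts in HGG and from 191 ± 67.5 to 777 ± 540 in EPN. Lars2 went from 8937 ± 1144 to 5105 ± 3354 in HGG and from 2306 ± 475 to 7031 ± 5061 in EPN. The mean of Rn45s rose in both, from 18222 ± 8503 to 31865 ± 30370 and from 7064 ± 644 to 53604 ± 43044.

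Limma called 920 of 15145 genes in this test of the difference, 431 upward and 489 downward, with 4106 at an unadjusted p under 0.05, 786 called by edgeR and 2427 by DESeq2. Camera's adjusted p was 5.34e-05 for neuron markers, 0.000851 for astrocyte markers, 0.0107 for microglia markers, 0.0263 for histone acetylation genes, and 0.00217 for hypoxia and immediate early genes. With an estimated correlation the adjusted p = 0.824 for each, except immediate early genes (adjusted p = 0.707 with an estimated correlation), whose call was also lost with a correction for GC content and length (adjusted p = 0.0951). Adjusted over the list alone, 5 histone acetylation genes were higher and 2 lower, and 7 immediate early genes were higher. The median was -0.996 for astrocyte markers and 0.53 for hypoxia genes without HGG control 1. The microglia call was lost without HGG control 2 (0.109, median -0.65), EPN Sox9-GOF 1 (0.0542) or EPN Sox9-GOF 3 (0.0552, median -0.79), and the histone acetylation call without HGG control 2 (0.0678), HGG Sox9-GOF 1 (0.0552), EPN Sox9-GOF 1 (0.0738) or EPN Sox9-GOF 3 (0.0552). The adjusted p of Sox9 was 0.0550 without HGG Sox9-GOF 2, 0.0588 without HGG Sox9-GOF 3, 0.0601 without EPN control 2 and 0.0662 without EPN control 3.

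The count of 920 moved with single libraries. It was 594 and 604 without HGG control 1 or 2, 2095 without HGG control 3, and 307, 233 and 91 without HGG Sox9-GOF 1, 2 or 3. It was 350, 48 and 35 without EPN control 1, 2 or 3, and 542 and 348 without EPN Sox9-GOF 2 or 3. The difference was higher in genes of higher GC content (Spearman rho 0.411 across genes). With a correction for GC content and length 108 genes were called, 72 of them shared with the 920, and Sox9 had a difference of -1.09 (adjusted p = 0.0710). Of the 31 genes named here or in the lists, 25 kept their call with the replicate number as a block. Dmrta2 (adjusted p = 0.0543), Klf2 (0.0570), Npy2r, Phlda1, Scg2 and Ugt8a did not. That block was common to the HGG and EPN libraries, although the EPN numbers did not pass the pairing check. Of the same 31, 4 kept their call after that correction (Gal, Hdac7, Scand1 and Ube2j2) and 3 with each library left out in turn (Scand1, Mta1 and Ier2). Across 14121 genes the fold changes of Sox9-GOF in HGG and EPN had a correlation of -0.25. By limma 0 genes were called in both, and DESeq2 called 89, of which 3 were higher in both, 11 lower in both and 75 opposite, against 97.6 and 48.3 opposite for independent lists (Fisher's exact test across genes, odds ratio 0.898, p = 0.378).

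The 2 control groups were set side by side last. Recovered reads of both deposited tables were rescaled together, and the labels name no batch. Sox9 was 4.03-fold higher in EPN controls than in HGG controls (log2 fold change 2.01, SE 0.19, limma adjusted p = 0.00429). Endothelial markers were higher in EPN by a median of 1.80, with 8 of 18 called, such as the junction gene Cdh5 (2.63, SE 0.30), and pericyte markers by 1.07, with 4 of 13 called, such as Pdgfrb (4.05, SE 0.25). Collagen and mesenchymal genes were higher by 1.48, with 6 of 26 called, among them the fibronectin gene Fn1 (3.63) and Lum (4.17, SE 0.41). Cartilage genes were higher by 1.99, with 4 of 16 called, among them Ucma (8.18, SE 0.59) and Col9a1 (4.04, SE 0.82), and microglia and macrophage markers by 0.93, with 3 of 23 called (Mrc1, Cx3cr1 and Tmem119). Oligodendrocyte precursor markers were lower by -1.76, with 6 of 16 called, including the lineage factors Olig1 (-3.05, SE 0.37) and Olig2 (-3.17, SE 0.41), and neuron markers by -0.93, with only Dcx called (-2.23, SE 0.29). Zfta (1.88, adjusted p = 0.0104) and Nf1 (1.05, adjusted p = 0.0163) were higher in EPN by limma, and of the genes described in ZFTA-RELA ependymoma 6 were called higher and 1 lower, with Lmx1b at 4.99, Igf2 at 6.50 and Wnt5a at 2.66. Of 16 tested members of the Sox family, Sox9 and Sox7 were higher and Sox3, Sox8, Sox12 and Sox21 lower. Signs of RNA or library quality differed between the same groups. Mir6236 had 191 ± 67.5 normalized counts (SD, n = 3) in EPN controls against 2539 ± 808 in HGG controls. Lars2 had 2306 ± 475 against 8937 ± 1144, and Rn45s 7064 ± 644 against 18222 ± 8503.

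Limma called 2339 of 14938 genes between the controls (1425 higher in EPN, 914 lower), with 5018 at an unadjusted p under 0.05, 2308 called by edgeR and 4311 by DESeq2. The groups did not overlap for 6071 genes, 40.6% against the average of 10% over splits, an excess that was not tested. Nr5a1, a steroidogenic transcription factor, had 2 reads in all HGG controls and 2980 ± 632 normalized counts (SD, n = 3) in EPN controls, a ratio of 4472 (95% counting interval 1238 to 36934). Upk3b, a uroplakin, had 0 reads in the HGG controls and 1567 ± 1349 normalized counts in EPN controls, at least 1423-fold higher with a floor of 3 reads over the group, where the lower 95% counting limit is 1157-fold. Among called decreases were Foxd3, with 696 ± 963 normalized counts in the HGG controls and 2 reads in all EPN controls, Sostdc1 (-5.89, SE 0.88) and the NOTCH ligand Dll3 (-4.52, SE 0.66). For Foxd3 the ratio of EPN to HGG controls was 0.00198 (95% counting interval 0.00024 to 0.00718). Foxd3 lost its call without EPN control 1, 2 or 3 (adjusted p = 0.0531, 0.0597 and 0.0542), and Sostdc1 (0.0508) and Dll3 (0.0546) without EPN control 2. Of 50 called genes followed, 48, 44 and 46 kept their call without HGG control 1, 2 or 3, and 31, 24 and 30 without EPN control 1, 2 or 3. Neural stem genes went both ways, with the Hedgehog effector Gli3 higher (3.75) and the NOTCH target Hes5 (-3.09) lower. The count was 3635 without HGG control 1, 649 without EPN control 1, 385 without EPN control 2 and 719 without EPN control 3.

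Camera's adjusted p between the controls was 1.27e-05 for endothelial markers (adjusted p = 0.724 with an estimated correlation) and for oligodendrocyte precursor markers (adjusted p = 0.804 with an estimated correlation). It was 0.00334 for pericyte markers and for collagen genes (adjusted p = 0.724 with an estimated correlation), 0.0121 for cartilage genes (adjusted p = 0.804 with an estimated correlation), and 0.00233 for microglia and 0.0267 for neuron markers (adjusted p = 0.918 with an estimated correlation). Adjusted over the list alone, 15 endothelial, 4 pericyte, 8 collagen, 6 cartilage and 2 microglia genes were higher, and 9 oligodendrocyte precursor markers and 1 neuron marker were lower. The cartilage call was lost without HGG control 3 (0.0593), and the neuron call without HGG control 2 (0.0546), HGG control 3 (0.512, median -0.06), EPN control 1 (0.0766) or EPN control 2 (0.0611). Without HGG control 1 the medians were 1.08 for cartilage genes, -1.97 for neuron markers and 1.61 for pericyte markers, and without HGG control 3 that of collagen genes was 0.89. Not passing were neutrophil markers (median 2.16, 6 of 6 positive, adjusted p = 0.0529), genes described in ZFTA-RELA ependymoma (0.46, 0.0529), cell cycle genes (0.45, 0.0529), mature oligodendrocyte markers (-0.80, 0.0529), erythroid genes (0.48 over 3 genes, 0.336), neural stem genes (-0.75, 0.244) and choroid plexus markers (-2.26, 0.366).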

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

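All tests of explanations in this part were chosen after the results had been seen, as were the GC correction and the shared-control simulation after that correction. The results below drew attention because the effect of Sox9-GOF differed between EPN and HGG by a test of the difference itself.

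Limma called 920 genes in that test, and 871 was the highest count among the other 99 of 100 drawn splits of the 12 libraries, out of 200 possible. Most of these splits break up the groups of both models, so their share does not test a difference between the models. The splits that keep the HGG groups whole and regroup the EPN libraries number 20, too few for a share under 0.05, and the highest others called 871, 720 and 710 genes. Those that keep the EPN groups whole also number 20, and the highest other called 8. Medians of 6 lists differed by camera, namely astrocyte markers -1.55, neuron markers -2.92, microglia markers -1.24, histone acetylation genes 0.32, hypoxia genes 1.04 and immediate early genes 1.46, and none of the 6 held with an estimated correlation (adjusted p = 0.707 for immediate early genes and 0.824 for the others). As many lists passed in 89 of the 100 drawn splits, up to 15, which does not test a difference between the models either. With the real split included, this held in 7 of the 20 splits that keep the HGG groups whole, up to 8. It held in 19 of the 20 that keep the EPN groups whole, up to 14. Sox9 differed by -1.36 on the log2 scale, from a mean of 1091 normalized counts in EPN controls and 271 in HGG controls. Among named gene models with a mean log2 CPM of at least 1, the largest differences upward were Scand1 (4.50), Mir6236 (4.44), Dmrta2 (3.82), Nrtn (3.56) and Ube2j2 (3.36), and downward Gal (-7.33), Tnn (-6.42), Npy2r (-5.89), Dgkb (-5.80) and Scg2 (-5.27). For each of these genes the mean in the libraries labelled Sox9-LOF lay on the same side of the HGG controls as in HGG Sox9-GOF. Scand1 had 763 normalized counts in the HGG controls, 51.3 in the libraries labelled Sox9-LOF and 74.8 in HGG Sox9-GOF. Gal had 3.15, 112 and 68.2 and Dgkb 129, 616 and 627 in that order. A feature of the HGG controls therefore cannot be told apart from an effect of Sox9-GOF in these genes. Called list members upward were Hdac7 (1.87), Mta1 (1.73), Kat2a (1.08), Ier2 (2.37), Egr1 (1.96), Klf2 (2.04), Tcf7 (2.52), Phlda1 (2.07), Bbc3 (1.55) and Rela (1.43). Called list members downward were Map2 (-1.83), P2ry12 (-2.98), Gatad2b (-1.61), Ptprz1 (-2.90), Ugt8a (-2.22), Rgs5 (-3.28), Lum (-3.25), Rfx3 (-2.09), Il17rd (-2.44) and Eda2r (-4.34).

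The first pattern weighed is that fold changes in the libraries labelled Sox9-LOF and in HGG Sox9-GOF went together (correlation 0.807). GC content and gene length stay open as part of the cause. Together they accounted for 19.4% of the variance of the fold changes in the libraries labelled Sox9-LOF and 32.1% in HGG Sox9-GOF. After GC content and length were removed the covariance was 0.358, against 0.533 before, and 19 of 100 simulated pairs of unchanged groups had one as large. It was 0.569 without HGG control 2 and 0.630 without HGG control 3, for which no pairs were simulated. A difference in RNA or library quality cannot be told apart where it follows the groups. In all 3 HGG controls Mir6236, whose reads went with those of Rn45s across the EPN Sox9-GOF libraries, lay above every other HGG library. Rn45s itself did not part the HGG groups, with normalized counts of 9499, 26486 and 18682 in the controls. It had 9886, 9611 and 7116.5 in the libraries labelled Sox9-LOF and 65718, 7015 and 22861 in HGG Sox9-GOF. Shared controls stay open: 21 of 100 simulated pairs of unchanged groups had a covariance as large as 0.533 (0.805 without HGG control 3), and the 3 HGG controls differ from each other more than replicates of other groups do. The simulated groups carried no pairing by replicate number. A common effect of higher Sox9, which both sets of libraries showed, is a biological candidate explanation that the design cannot separate from the shared controls.

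The second pattern is the lower neuron, glial and vascular markers in EPN Sox9-GOF. GC content and length are argued against as the whole cause, since the neuron median was -2.04 after that correction, against -2.25 before. A smaller share of brain tissue around the tumour would lower all markers of that tissue, and neuron and mature oligodendrocyte scores went down alike (-1.98 ± 0.674 and -1.40 ± 0.612, SE), with a difference of -0.581 (SE 0.538). Endothelial markers (-0.581 ± 0.270) and microglia markers (-0.462 ± 0.427) went down less, with differences from neuron markers of -1.40 (SE 0.494) and -1.52 (SE 0.688). Astrocyte, precursor and pericyte markers differed from neuron markers by -0.759 (SE 0.599), -0.830 (SE 0.604) and -1.22 (SE 0.762), within 2 SE. The endothelial and microglia values go against a smaller brain share as the whole cause, unless vessels and macrophages of the tumour itself make up for the loss, which was not tested. A difference in RNA or library quality cannot be told apart, since the ribosomal RNA precursor Rn45s was higher in each EPN Sox9-GOF library than in each EPN control. Within the 5 groups the neuron score had a slope of 0.0924 (SE 0.342) on log2 Rn45s, which predicts a change of 0.241 (SE 0.894) against the -1.98 seen, 1.99 SE apart, and the slopes of the 6 other lists lay within 2 SE of 0. A change of tumour cell state with Sox9-GOF stays open as a biological explanation, since tumour cells may express astrocyte and precursor genes, and bulk tissue does not separate them.

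The third pattern is the higher Sox9 in the libraries labelled Sox9-LOF. GC content and length as the whole cause are argued against, since the log2 fold change was 0.98 after correction (SE 0.307, limma adjusted p = 0.502), against 1.03 before. An exchange of labels cannot be told apart from a true group: all 3 libraries labelled Sox9-LOF lay above every HGG control, no control lay among them, and the reads per gene do not show which alleles were present. A larger share of astrocyte-like cells, which express Sox9, cannot be told apart either, because the astrocyte median was 0.91 with all libraries, close to the 1.03 of Sox9, and 1.41 without HGG control 2, but 0.21 without HGG control 1, where Sox9 was at 0.88. A biological explanation that was not tested is that a nonfunctional Sox9 transcript might still be made, which reads summed over the gene do not show.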

How the results depend on the processing

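The shared spread of the 9 HGG libraries, library weights, the pseudocounts, TMM scaling on the log scale, edgeR's own filter and the GC and length correction were chosen after the results had been seen, and the other alternatives were planned. The cause of a change was not tested unless stated. With other tools, DESeq2 called 1221 genes for the libraries labelled Sox9-LOF, 2174 for HGG Sox9-GOF, 851 for EPN Sox9-GOF, 2427 for the difference between models and 4311 between controls, where limma called 0, 0, 0, 920 and 2339. In 20 simulations of unchanged HGG groups DESeq2 called a median of 1.5 and at most 5223 genes in place of the libraries labelled Sox9-LOF. In place of HGG Sox9-GOF it called a median of 0 and at most 5299. With the spread shared by all 15 libraries, limma called 1108, 2253, 129, 1511 and 4204, and with that of the 9 HGG libraries 323 and 1259. Library weights gave 1 in the libraries labelled Sox9-LOF. The GC and length correction gave 108 for the difference. TMM scaling moved its split from 431 upward and 489 downward to 361 and 572. Genes called by DESeq2 in both HGG comparisons were 850 (290 by limma with the shared HGG spread), and in Sox9-GOF of both models 89 (28 by limma with the spread of all 15).

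With 1 library left out in turn, the counts ranged from 0 to 6 (without HGG control 2) for the libraries labelled Sox9-LOF, 0 to 5 (without EPN control 1) for EPN Sox9-GOF, 35 (without EPN control 3) to 2095 (without HGG control 3) for the difference and 385 (without EPN control 2) to 3635 (without HGG control 1) between controls. The lists past camera ranged from 3 (without HGG control 1 or 3) to 7 for the libraries labelled Sox9-LOF, from 2 (without Sox9-GOF 2) to 8 (without HGG control 2) for HGG Sox9-GOF, from 7 (without Sox9-GOF 1) to 13 for EPN Sox9-GOF and from 4 (without EPN Sox9-GOF 1) to 10 (without HGG control 2) for the difference. The neuron median for the libraries labelled Sox9-LOF ranged from 0.13 (without HGG control 1) to 1.67 (without HGG control 3). With an estimated correlation 0 lists passed in each of the 5 comparisons, with a pseudocount of 8 4 lists passed for the libraries labelled Sox9-LOF, and with the GC correction 6 for HGG Sox9-GOF, with or without the block.

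The log2 fold change of Sox9 was 1.07 by DESeq2 and 1.04 with the spread of all 15 for the libraries labelled Sox9-LOF. It was 2.39, 2.38 and 2.39 (spread of the 9 HGG libraries) for HGG Sox9-GOF, and 1.05 by DESeq2 for EPN Sox9-GOF. The difference for Sox9 was -1.09 with the GC correction and -1.52 to -1.21 with 1 library left out. Nf1 changed sign in each Sox9 comparison. It was -0.34 with the GC correction for the libraries labelled Sox9-LOF and -0.12 for HGG Sox9-GOF (with the block too), and in EPN Sox9-GOF -0.0098 with the spread of all 15, -0.15 without Sox9-GOF 3, -0.05 without EPN control 1 and up to 0.22 without Sox9-GOF 2.

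The replicate number as a block gave 0 calls for each of the 3 Sox9 comparisons, 812 for the difference and 1129 between controls. In HGG Sox9-GOF, where the numbers may pair the samples although HGG control 3 correlated best with Sox9-GOF 1, it changed the call of astrocyte markers and no other. Elsewhere the samples share only a number, again not every sample correlated best with its own, and same-numbered deviations correlated at -0.14, 0.07 and 0.20 for the libraries labelled Sox9-LOF, -0.10, 0.02 and 0.30 for EPN Sox9-GOF and 0.24, -0.28 and -0.02 between controls. Over all named genes, 2185 of the values under other settings kept direction and side of the threshold, 130 passed it anew, 77 no longer passed and 4 changed sign. With 1 library left out these were 1100, 5, 255 and 2. Named genes of the 3 Sox9 comparisons, where limma called 0, could not lose a call. All losses came from the difference between the models and from the controls. There 3 of 31 and 24 of 50 called genes kept their call with each library left out in turn. For lists, 207 kept it and 41 lost it under other settings, and 194 kept it, 51 lost it and 1 changed direction with 1 library left out. In the simulated data genes were drawn independently, with a dispersion that followed the trend over genes and not a value for each gene. The shares recovered may therefore be too high for the real libraries. At that dispersion limma recovered 43.4%, 45.8%, 83.3%, 15.5% and 48.0% of simulated changes of 2 on the log2 scale in the 5 comparisons in the order above. At a dispersion 10 times smaller it recovered 100%, 99.0%, 100%, 96.9% and 99.0%. Of simulated changes of 1 it recovered 2%, 0%, 18.6%, 1.02% and 5.15% at the dispersion of the trend.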

Other observations

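All comparisons and genes in the first paragraphs of this part were chosen after the values had been seen. HGG Sox9-GOF was set directly against the libraries labelled Sox9-LOF, without the controls. Microglia and macrophage markers were higher with Sox9-GOF by a median log2 fold change of 0.71, cartilage targets of SOX9 by 0.61, lymphocyte markers by 1.52 and interferon genes by 0.84, while immediate early genes were lower by -1.33, ERK feedback genes by -0.59, endothelial markers by -0.52 and mature oligodendrocyte markers by -0.71. Camera's adjusted p was 3.31e-13 for microglia markers, 1.21e-08 for immediate early genes, 1.42e-06 for ERK feedback genes and 2.57e-06 for cartilage genes (adjusted p = 0.495 with an estimated correlation for each). It was 2.40e-05 for lymphocyte markers (adjusted p = 0.558 with an estimated correlation), 0.000213 for interferon genes (adjusted p = 0.749 with an estimated correlation), 0.000372 for endothelial markers (adjusted p = 0.495 with an estimated correlation) and 0.00355 for mature oligodendrocyte markers (adjusted p = 0.732 with an estimated correlation). In all, 14 lists passed, and this comparison was not rerun with libraries left out. The rest of the 14 were all lower by camera. These were astrocyte markers (median -0.38, adjusted p = 0.00902), cilia genes (-0.53, 0.0127) and genes described in ZFTA-RELA ependymoma (-0.44, 0.0127). Neural stem genes (-0.21, 0.0183), WNT targets (-0.39, 0.0278) and hypoxia genes (-0.10, 0.0297) were lower too. None of these passed with an estimated correlation (adjusted p of 0.495 to 0.749). Limma called 0 of 14941 genes, with 1100 at an unadjusted p under 0.05, 0 by edgeR, and 77 higher and 55 lower by DESeq2. Sox9 was higher by 1.35 (SE 0.25, limma adjusted p = 0.474).

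Hoxb9, a patterning gene of the posterior body axis, had 0 reads in all 9 HGG libraries, 1, 1 and 0 in the EPN controls, and 36, 28 and 72 in EPN Sox9-GOF 1, 2 and 3. Other posterior genes did not follow it: Hoxa9 had 167, 0 and 0 reads and Hoxa10 had 285, 1 and 0 in the same libraries. Its normalized count was 39.8 ± 25.4 (SD, n = 3) with Sox9-GOF and 0.728 ± 0.631 in the EPN controls, and limma's adjusted p was 0.133. Several genes stood high in the HGG controls against every other group. Scand1 had 763 ± 196 normalized counts there, and 51.3 ± 7.81 in the libraries labelled Sox9-LOF, 74.8 ± 14.8 in HGG Sox9-GOF, 117 ± 55.4 in EPN controls and 252 ± 70.4 in EPN Sox9-GOF. Zfp771, a zinc finger gene, had 348 ± 23.8, 64.4 ± 6.19, 80.5 ± 11.2, 85.7 ± 20.9 and 193 ± 31.4 in the same order, and Erdr1 had 3341 ± 871, 514 ± 211, 457 ± 241, 452 ± 75.0 and 713 ± 615. Rn45s, the ribosomal RNA precursor, which poly(A) selection should largely remove, had 18222 ± 8503, 8871 ± 1526, 31865 ± 30370, 7064 ± 644 and 53604 ± 43044.

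Sex-linked genes differed within and between groups, so the libraries labelled Sox9-LOF, the HGG Sox9-GOF libraries and the EPN controls each come from more than 1 animal. Xist, transcribed from the inactive X chromosome, had normalized counts of 4920, 4617 and 2797 in the HGG controls, with Ddx3y, a gene of the Y chromosome, at 0 in all 3. In the libraries labelled Sox9-LOF Xist was 1.17, 4345 and 0 and Ddx3y 794, 1.14 and 1021. In HGG Sox9-GOF Xist was 4508, 9.54 and 8947 and Ddx3y 0.718, 527 and 0. In EPN controls Xist was 7.39, 5110 and 4666 and Ddx3y 873, 3.38 and 0, and in EPN Sox9-GOF Xist was 0, 0.872 and 0 and Ddx3y 1069, 443 and 1240. By these genes the sexes were unevenly spread between the groups of each comparison. No test here took sex into account, so a part played by sex in any change was not tested.

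Splits of 6 libraries into groups of 3 number 10, too few for a share under 0.05. Real splits gave 0 called genes in each of the 3 Sox9 comparisons, where the highest other split also gave 0 (10 of 10 splits as large), and 2339 between controls, where the highest other gave 0 (1 of 10). For lists past camera the real splits gave 7, 3, 12 and 7 for the libraries labelled Sox9-LOF, HGG Sox9-GOF, EPN Sox9-GOF and the controls, and the highest others gave 17, 16, 14 and 16, with 10, 10, 2 and 8 of 10 splits as large. For the libraries labelled Sox9-LOF and HGG Sox9-GOF, every other grouping thus gave at least as many lists. The number of lists there does not set the real groups apart. In HGG Sox9-GOF, splits that part as many pairs gave at most 11 lists. Counts several times the real one point to a structure of the libraries, but not to 1 control: HGG control 2 was set apart from controls 1 and 3 in the splits with 17 lists and with 16 between controls, and control 3 or control 1 was in the 2 splits of HGG Sox9-GOF with 16.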
